A study of Neurospora crassa with 16 samples.

How the data were processed

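RNA was measured in mycelia of the filamentous fungus Neurospora crassa, a wild type (WT) and a strain labelled as a deletion of stk-12, which encodes a serine/threonine protein kinase. Both strains were grown from conidia on Avicel, a crystalline cellulose that serves as the carbon source, and were harvested after 12 h, 1 day, 3 days and 5 days. The 2 genotypes and 4 times gave 8 groups of 2 libraries, 16 libraries in all. Groups and replicate numbers were taken from the labels. The labels do not say that the replicates were separate cultures, so p-values measured only the spread between these samples, which may be technical. No pair of replicates was identical within sampling noise: the chi-square per degree of freedom between the counts of replicates ran from 4.00 (WT 1d) to 22.6 (WT 5d), so every library was counted separately.

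The deposited table held, per the file headers, read counts per gene (count) and RPKM values, which scale reads by gene length and library total, for 9730 genes in each library. Per the submitters' processing notes, TopHat2 (2.0.8b), a spliced read aligner, and HTSeq (0.5.4p3), which assigns reads to genes, were named as tools. Neither the genome build nor the strand used in counting was given in the sources used here, so the values of antisense, overlapping and near-identical genes are uncertain. Product names came from the deposited table. A reference table (assembly NC12) supplied chromosomes, the order of loci by start position, and symbols, with deposited symbols used where it had none. Positions on the genome served no other purpose. Of the gene identifiers, 9729 were in that table and 1936 genes had a symbol. The RPKM values deposited by the authors were checked against the counts: all 146267 values above 0 (100%) equalled the count divided by the library's gene total and a fixed gene length within a relative tolerance of 0.001. Only the counts were used in the tests. In 2 libraries, 6 entries that named no gene, such as reads without a feature, were left out. The last of them repeated the library's total of gene reads. The others held 6.86% of the reads of WT 3d replicate 2 and 4.43% of those of mutant 5d replicate 1.

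Reads assigned to genes ran from 14946389 (WT 1d replicate 1) to 26466759 (mutant 12h replicate 1). The totals of replicates 1 and 2 were 25027909 and 24796091 (WT 12h), 14946389 and 16356873 (WT 1d), 20791971 and 17790889 (WT 3d), 15913067 and 15309632 (WT 5d), 26466759 and 25841965 (mutant 12h), 16589245 and 18354795 (mutant 1d), 19583199 and 20993981 (mutant 3d), and 18336221 and 22731924 (mutant 5d). The most abundant gene took up to 6.94% of a library (ccg-4 in WT 5d replicate 1). TMM factors ran from 0.840 to 1.25, with the lowest values at 12h and in WT at 1d and the highest in WT at 5d.

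Analyses used R (4.3.3) with edgeR (4.0.16), limma (3.58.1) and DESeq2 (1.42.0), and Python (3.11.15) with pandas (2.3.3), NumPy (2.4.6) and SciPy (1.17.1). Genes with low counts were removed with filterByExpr over the 8 groups, which left 8983 genes and removed 747. Counts were scaled by TMM, and levels are given as CPM, counts relative to the library size scaled in that way, as mean ± SD of 2 libraries. A quasi-likelihood model in edgeR with 1 mean per group was fitted to all 16 libraries. It had 8 residual degrees of freedom and a common biological coefficient of variation of 0.0685. Each test was a contrast of group means: mutant against WT at each time and averaged over the 4 times, whether the genotype difference was equal at the 4 times (an F test on 3 degrees of freedom), and each WT step in time. A value given after camera is its adjusted p. Adjusted p-values of genes followed Benjamini and Hochberg over all genes tested, with 0.05 as the threshold. Log2 fold changes are mutant minus WT, or later minus earlier time. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. The replicate numbers were not taken to pair samples.

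Power was tested on simulated data with the same depth, spread and group sizes, in which 50 genes each were raised or lowered by 1.25, 1.5, 2 and 4-fold. At 12h, 1d, 3d and 5d, 30, 24, 30 and 32% of 1.25-fold changes were recovered, 76, 72, 74 and 84% of 1.5-fold changes, 92, 82, 98 and 98% of 2-fold changes, and 100% of 4-fold changes at each time. Of the calls, 4.49, 2.80, 6.79 and 4.27% were false. These simulated contrasts called 156, 143, 162 and 164 genes, against 1172, 3337, 5342 and 5530 in the real data. The Benjamini and Hochberg threshold is looser where more genes differ, so these rates do not describe the real contrasts.

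The tests, alternatives, rule for naming genes and 23 gene lists were fixed before the data were examined. The lists were cellulases, oxidative cellulose degradation (lytic polysaccharide monooxygenases and cellobiose dehydrogenase), beta-glucosidases, hemicellulases, sugar and cellodextrin transporters, regulators of plant cell wall enzymes, starch and sucrose enzymes, pectin enzymes, conidiation and carotenoid genes, light response and clock, glycolysis, gluconeogenesis and C2 metabolism, endoplasmic reticulum (ER) folding, mating type A locus, secretory pathway, cytosolic ribosomal proteins, ribosome biogenesis, proteasome, respiratory chain and ATP synthase, heat shock and chaperones, peptidases, cell wall synthesis and remodelling, and histones and DNA replication. The last 9, from the secretory pathway onward, were collected from product names, and the others were lists of genes. The conidiation list served as a marker of conidia, the other cell type that a mycelial harvest can hold. Each list was tested with camera, which asks whether its genes moved further in 1 direction than other genes, with a preset correlation between genes of 0.01, and the p-values were adjusted over the 115 tests of 23 lists in 5 genotype contrasts. Beside it, camera with a correlation estimated from the residuals, and fry, were run. The fry test asks whether the genes of a list moved on balance 1 way and does not compare them with other genes. Of the camera calls in the 5 genotype contrasts, only those of the mating type A list at 12h and for the mean of the 4 times held with the estimated correlation. In simulated data, a list raised 2-fold gave camera p = 2.8e-39 with the preset and 8.25e-07 with the estimated correlation, and 15 and 13 of 200 random lists had a p under 0.05. The simulated genes were drawn independently of each other. They cannot show how either test behaves with correlated genes, such as the cellulases (estimated correlation 0.719 to 0.747). Counts of list members that rose or fell are over all genes tested, and in the genotype contrasts counts adjusted over the list alone are given where they differ. Whether a list's genotype difference changed between consecutive times was tested in the same way, in 69 tests.

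The genes named were stk-12, a fixed panel of 18 genes of cellulose degradation and its regulators, up to 2 rising and 2 falling members of each list with the smallest p at each contrast, and the 5 largest rises and falls at each time among genes with a mean of at least 5 CPM whose mutant libraries both lay on the same side of both WT libraries. For the mean of the 4 times, the sign had to be equal at each time. For WT steps, the panel and the 3 largest rises and falls were named. This gave 224 genes. A gene named outside this rule is said to have been chosen after its values were seen.

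The alternatives tried were DESeq2 size factors in edgeR, library totals without TMM, no filter on low counts, DESeq2, limma voom, a replicate block, a fit to only the groups compared, and leaving out each library in turn. Added after the data were seen were counts without the mating type genes and the 50 loci on each side of matA-1 (101 tested genes left out), and means over 3 of the 4 times. Scaling by totals alone moved the median log2 fold change of all genes at 1d to 0.18 (0.02 with TMM), at 3d to -0.25 (-0.02), at 5d to -0.11 (-0.01), and for WT 3d against 1d to 0.59 (0.11). Directions below are therefore relative to the TMM scaling. Where a list's direction is given below and turned with totals, this is said, and the figure of list medians marks each median whose sign turned. A fold against a group with 0 reads in both libraries is a lower bound against a floor of 3 counts per library. Such bounds and counting intervals cover counting error only.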

Results

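stk-12 itself, the gene the mutant was labelled as lacking, was lower in the mutant at all 4 times but was not absent. WT held 43.1 ± 0.127, 39.3 ± 1.54, 102 ± 3.18 and 109 ± 1.70 CPM at 12h, 1d, 3d and 5d, and the mutant 16.5 ± 0.255, 9.63 ± 0.533, 35.8 ± 2.65 and 47.2 ± 1.17 CPM (mean ± SD, n = 2 libraries). The mutant thus kept 38.2, 24.5, 35.0 and 43.3% of the WT level. In counts, the mutant libraries held 386 and 371, 155 and 161, 761 and 706, and 1021 and 1190 reads of stk-12, against 905 and 932, 483 and 556, 2429 and 2233, and 2065 and 2108 in WT. Every mutant library lay below both WT libraries of its time. The log2 fold change was -1.39 ± 0.076 (SE) at 12h (edgeR, adjusted p = 3.93e-09), -2.03 ± 0.088 at 1d (1.59e-10), -1.52 ± 0.0699 at 3d (1.41e-11) and -1.21 ± 0.0683 at 5d (3.57e-10). Counts per gene cannot show where in the gene the remaining reads lay, nor whether they came from an overlapping transcript or from nuclei without the deletion, so a pure deletion strain is not shown. Admixture of the WT strain sequenced here is argued against as their source. The mating type A gene matA-1 had 0 reads in each mutant library, against at least 350 in each WT library.

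**Figure D1:**
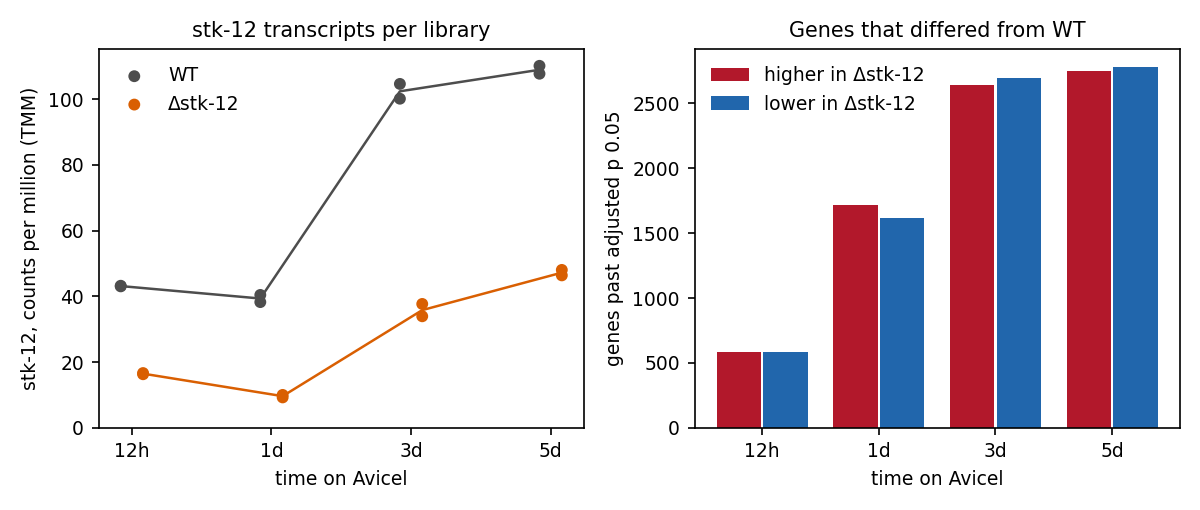
Left, level of stk-12 in each library in TMM-scaled CPM, with lines through the means of 2 libraries. Right, number of genes higher and lower in the mutant than in WT at each time (edgeR, adjusted p under 0.05).

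The strains also differed in mating type transcripts. The mating type A genes matA-1, matA-2 and matA-3, which specify mating identity, had 0 reads in all 8 mutant libraries. Against a floor of 3 counts per library, matA-1 was at least 237, 153, 1221 and 773-fold lower in the mutant at 12h, 1d, 3d and 5d, matA-2 at least 17.1, 4.89, 76.3 and 46.3-fold, and matA-3 at least 31.1, 9.09, 232 and 135-fold. The median of the list with its members at these bounds was the value of matA-3. ccg-4, the pheromone gene of mating type A, had at most 3 reads in a mutant library, against 47789 and 50995 reads in WT at 12h and 1104419 and 811397 at 5d, where it reached 49995 ± 10755 CPM and was the most abundant WT transcript. Its ratio at 5d, from 4 mutant reads, was 586460-fold lower (95% counting interval 229050 to 2152410). mfa-1, the pheromone gene of the opposite mating type a, stood at 9722 ± 153, 1494 ± 2.12, 5194 ± 1078 and 3449 ± 132 CPM in the mutant and at 2.13 ± 0.858, 1.60 ± 0.204, 16.2 ± 2.33 and 21.3 ± 1.38 CPM in WT. The receptor gene pre-2 had log2 fold changes of 6.11, 6.74, 4.69 and 1.98. The camera test put the mating type A list lower at every time (adjusted p = 1.34e-31 at 12h, 3.83e-10 at 1d, 8.26e-10 at 3d and 4.66e-10 at 5d). With an estimated correlation the adjusted p was 0.00399 at 12h and 0.0574 at each later time. All 8 mutant libraries lacked mating type A transcripts and all 8 WT libraries held them, so every genotype difference below is also a difference between strains that differ in these transcripts.

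**Figure D2:**
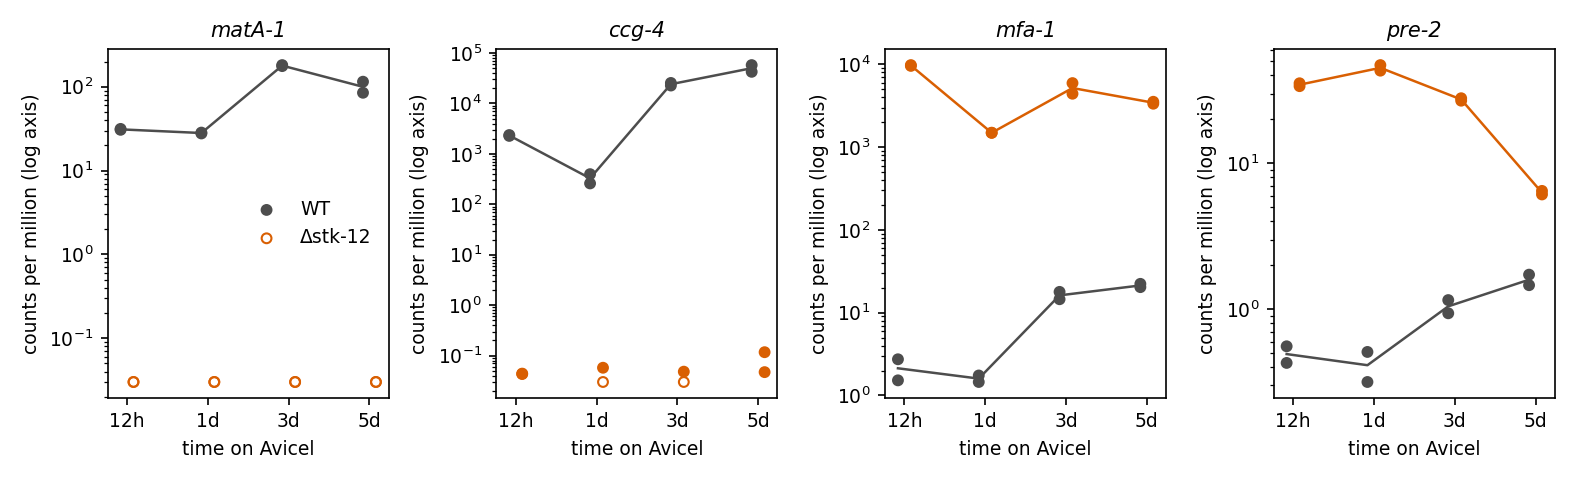
Levels of the mating type A genes matA-1 and ccg-4 and of the mating type a genes mfa-1 and pre-2 in each library, in CPM on log axes. Open circles mark libraries with 0 reads, drawn at a fixed low value, and lines join means of groups without such libraries.

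At 12h the main cellulose-degrading enzymes were already among the most abundant transcripts, and most of them differed little between the strains. cbh-1, the major cellobiohydrolase, stood at 26960 ± 750 CPM in the mutant and 27160 ± 1626 CPM in WT (log2 fold change -0.01, adjusted p = 0.969), and gh6-2, gh5-1, cdh-1 and gh10-1 had log2 fold changes of -0.05, -0.07, -0.12 and -0.17, none past the test. gh6-3 had a log2 fold change of -0.33 (adjusted p = 0.0533) and passed with library totals alone (0.0367) and with DESeq2 size factors (0.0495). Some hemicellulases and most pectin enzymes were lower. Of 24 hemicellulases, 12 fell and 0 rose (15 and 0 over the list alone; median -0.33). Among them were the arabinofuranosidase gh54-1 (-1.82 ± 0.171) and the cellulose-binding lipase NCU09416 (-0.97 ± 0.0859). Of 6 pectin enzymes 4 fell (5 over the list alone; median -0.55), with ce12-1 at -0.74 and the polygalacturonase gh28-1 at -0.61. Of 10 sugar transporters, 5 rose (6 over the list alone; median 0.40), including the cellodextrin transporter cdt-1 (0.52 ± 0.108), NCU00821 (0.66) and hgt-1 (0.43). The camera adjusted p was 1.46e-08 for hemicellulases, 0.000226 for pectin enzymes and 7.21e-05 for transporters, and 0.437, 0.272 and 0.359 with an estimated correlation.

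At 12h, of 15 genes of oxidative cellulose degradation, 5 fell, with gh61-9 at -0.47 and gh61-7 at -0.39 (camera adjusted p = 0.0412; adjusted p = 0.693 with an estimated correlation), while 2 of 9 cellulases fell, gh7-2 (-0.42) and gh45-1 (-0.38), and 4 over the list alone (camera adjusted p = 0.183). Genes of gluconeogenesis and C2 metabolism rose in 3 of 7 cases (4 over the list alone), with acu-6, phosphoenolpyruvate carboxykinase, at 1.27 and acu-9, malate synthase, at 0.48 (camera adjusted p = 0.0066; adjusted p = 0.3 with an estimated correlation). Of 38 ribosome biogenesis genes, 9 fell (19 over the list alone; median -0.27; camera adjusted p = 1.09e-05; adjusted p = 0.693 with an estimated correlation), and of 77 cytosolic ribosomal proteins 1 fell, un-16 (-0.66), while the list as a whole lay slightly lower (median -0.13; camera adjusted p = 0.00292; adjusted p = 0.786 with an estimated correlation). Of 30 proteasome genes 5 rose, with rpn-1 at 0.24 (camera adjusted p = 0.00237; adjusted p = 0.693 with an estimated correlation). The carboxypeptidase NCU05980 fell by 2.96 on the log2 scale (12.1 ± 0.707 against 94.1 ± 4.23 CPM). The uncharacterised genes NCU01298 (164 ± 16.5 against 8.40 ± 0.248 CPM), NCU07201 (2.64) and NCU04616 (2.39) were the largest rises after mfa-1 and pre-2, and NCU09968, at 0 reads in the mutant, was at least 579-fold lower.

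In all, 1172 of 8983 genes differed at 12h, 587 higher and 585 lower (44 and 60 of them at least 2-fold). The count rested on few libraries: it was 463 without WT 12h replicate 1 and 541 without mutant 12h replicate 2. With library totals alone the split was 665 higher and 423 lower.

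At 1d most cellulases still ran close to WT. cfp, which encodes pyruvate decarboxylase, the enzyme that leads pyruvate toward ethanol, stood at 108 ± 33.4 CPM in the mutant and 2096 ± 377 CPM in WT (log2 fold change -4.28 ± 0.178), adh-1, an alcohol dehydrogenase, fell by 1.95, and acu-6 fell by 2.35. Of 11 glycolysis genes 7 fell and 0 rose (9 and 0 over the list alone, 4 and 1 with library totals alone; median -0.29), including gpd-1 (-0.59). eor-1, an ER oxidoreductase that forms disulfide bonds, fell by 1.83 (57.1 ± 6.51 against 204 ± 33.2 CPM), and eas, the rodlet protein that coats conidia, stood at 2.53 ± 0.0778 against 22.1 ± 5.13 CPM. The camera adjusted p for glycolysis was 5.5e-05, and 0.359 with an estimated correlation.

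Among the regulators at 1d, the activators of cellulase and xylanase genes clr-2 (0.89 ± 0.147), xlr-1 (0.84 ± 0.0766) and clr-1 (0.44 ± 0.0746) rose, and cre-1, the repressor that acts under preferred carbon sources, fell by 1.05 (147 ± 49.6 against 305 ± 21.1 CPM). In all, 6 of 10 regulators rose and 2 fell (camera adjusted p = 0.113, and 0.0414 with library totals alone). Of 9 cellulases 1 rose, gh7-4 (0.74), and 2 fell, gh7-1 (-0.37) and gh6-3 (-0.37; not past the test with library totals alone, adjusted p = 0.0584), with a median of -0.10 that turned positive (0.06) with library totals alone, and of 15 oxidative genes 1 rose and 4 fell, with gh61-9 and gh61-12 each at -0.64 and a median of -0.14 that also turned (0.01). Hemicellulases fell in 9 of 24 cases and rose in 1 (median -0.19), with gh11-1, a xylanase, at -1.07 and gh10-3 at -0.98 (camera adjusted p = 0.00372; adjusted p = 0.693 with an estimated correlation). NCU00821 (0.94) and the permease NCU06138 (0.63) were among 5 of 10 transporters that rose (6 over the list alone), and 1 fell (camera adjusted p = 0.113).

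At 1d, of 77 ribosomal proteins 51 fell and 0 rose (58 and 1 over the list alone, 14 and 2 with library totals alone; median -0.25, and -0.09 with totals), with un-16 at -0.74 and crp-77 at -0.37 (camera adjusted p = 6.73e-07; adjusted p = 0.651 with an estimated correlation). Of 56 genes of the respiratory chain and ATP synthase 28 fell and 1 rose (32 and 1 over the list alone; median -0.19; camera adjusted p = 0.000734; adjusted p = 0.651 with an estimated correlation). With library totals alone 5 fell and 5 rose (median -0.03), so the fall of this list depends on the scaling. Cell wall genes fell in 15 of 30 cases and rose in 4, with the glucanosyltransferase gel-4 at -1.20 (camera adjusted p = 0.0066; adjusted p = 0.626 with an estimated correlation). Of 14 conidiation genes 6 fell (7, with 1 risen, over the list alone), with con-8 at -1.02 (camera adjusted p = 0.0117; adjusted p = 0.651 with an estimated correlation). Histone and replication genes rose in 11 of 34 cases, with pole-2 at 0.71 (camera adjusted p = 0.0297; adjusted p = 0.693 with an estimated correlation). Further, 10 of 38 ribosome biogenesis genes rose (camera adjusted p = 0.0431; adjusted p = 0.828 with an estimated correlation). With library totals alone 19 histone and replication genes and 25 ribosome biogenesis genes rose. Of 38 secretory pathway genes 13 fell and 1 rose, of 30 proteasome genes 16 fell and 2 rose (17 and 2 over the list alone), and of 86 peptidases 27 fell and 6 rose, but with library totals alone these became 1 fallen and 7 risen, 1 and 3, and 11 and 22, so that their direction turned with the scaling. Their camera adjusted p was 0.0427, 0.0109 and 0.00173 (0.626, 0.734 and 0.362 with an estimated correlation), and with library totals alone the secretory pathway (0.278) and the proteasome (0.0893) no longer passed. ER folding genes (2 fallen, 0 risen) and starch and sucrose enzymes (3 and 1) also turned with totals, to 1 fallen and 3 risen, and 1 and 2. Among the peptidases NCU05980 (-3.47) and NCU06939 (-1.83) fell.

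At 1d, 3337 genes differed, 1718 higher and 1619 lower (175 and 212 at least 2-fold). The split was 3037 and 755 with library totals alone, and the count was 2100 without WT 1d replicate 1 and 2176 without mutant 1d replicate 1.

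At 3d the strains parted. In WT the cellulases had fallen to 1.71 ± 0.0590% of all counts from 5.08 ± 0.00225% at 1d, whereas in the mutant they stood at 6.36 ± 0.518%. cbh-1 stood at 30585 ± 3797 CPM in the mutant against 7776 ± 453 CPM in WT (log2 fold change 1.98 ± 0.115, edgeR adjusted p = 2.56e-10), the exoglucanase gh6-3 at 11415 ± 1478 against 700 ± 64.5 CPM (4.03 ± 0.12), cellobiose dehydrogenase cdh-1 at 8064 ± 1034 against 1248 ± 122 CPM (2.69 ± 0.119) and the xylanase gh10-1 at 7274 ± 682 against 540 ± 26.4 CPM (3.75 ± 0.156). All 9 cellulases rose (median 1.98), including gh6-2 (1.93), gh5-1 (1.73), gh7-1 (1.38) and gh7-4 (2.63). Of 15 oxidative genes 12 rose and 1, NCU07974 (-0.77), fell (median 2.44), with gh61-12 at 4.32, gh61-9 at 3.31, gh61-5 at 2.41 and gh61-1 at 1.82. Of 24 hemicellulases 19 rose and 2 fell (median 1.99), with gh43-6 at 3.67, gh11-1 at 2.84 and NCU09416 at 2.57. Of 6 pectin enzymes 5 rose (median 2.75), with the pectate lyase ply-1 at 4.24 and ce12-1 at 3.45. The camera adjusted p was 3.48e-12 for cellulases, 4.12e-14 for oxidative genes, 4.9e-17 for hemicellulases and 2.45e-07 for pectin enzymes, and 0.248, 0.113, 0.248 and 0.113 with an estimated correlation. These 4 calls rest on the preset correlation. Conidiation genes, the marker of the other cell type, moved the other way, with 10 of 14 lower in the mutant at 3d, as given below.

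**Figure D3:**
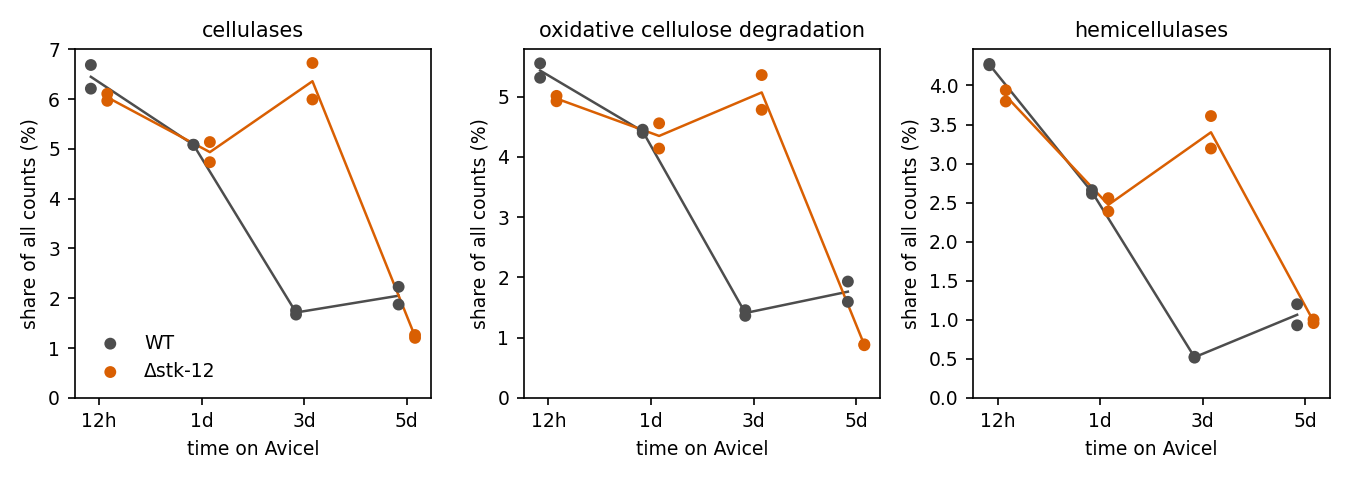
Share of all counts in each library that fell on the cellulases, the genes of oxidative cellulose degradation and the hemicellulases, in percent. Lines join the means of 2 libraries, and the shares do not depend on the scaling between libraries.

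The activator clr-2 stood at 627 ± 65.1 against 239 ± 7.99 CPM at 3d (1.39 ± 0.146) and clr-1 rose by 0.53, whereas xlr-1 (0.10, adjusted p = 0.27) and cre-1 (0.38, adjusted p = 0.082) did not pass. Of 10 regulators 5 rose and 3 fell (camera adjusted p = 0.916), with vib-1 at 0.75, NCU01856, the hac1-like activator of the unfolded protein response, at 0.78, rca-1 at -3.45 (16.8 ± 1.17 against 183 ± 4.45 CPM) and NCU05064 at -0.65. Transporters moved apart: cdt-1 rose by 0.86, while NCU00821 (-4.52; 60.2 ± 5.32 against 1382 ± 33.2 CPM) and hgt-1 (-1.21) fell, so that 3 of 10 rose and 5 fell (median -0.50; camera adjusted p = 0.0388; adjusted p = 0.651 with an estimated correlation). cdt-2 rose by 0.30 (adjusted p = 0.0335), a call that ended with library totals alone (0.07, adjusted p = 0.529). Of the 7 beta-glucosidases 4 rose (5 over the list alone), gh3-4 (1.80) and gh1-1 (0.84) among them, and 1, gh3-3 (-0.44), fell (camera adjusted p = 0.169).

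**Figure D4:**
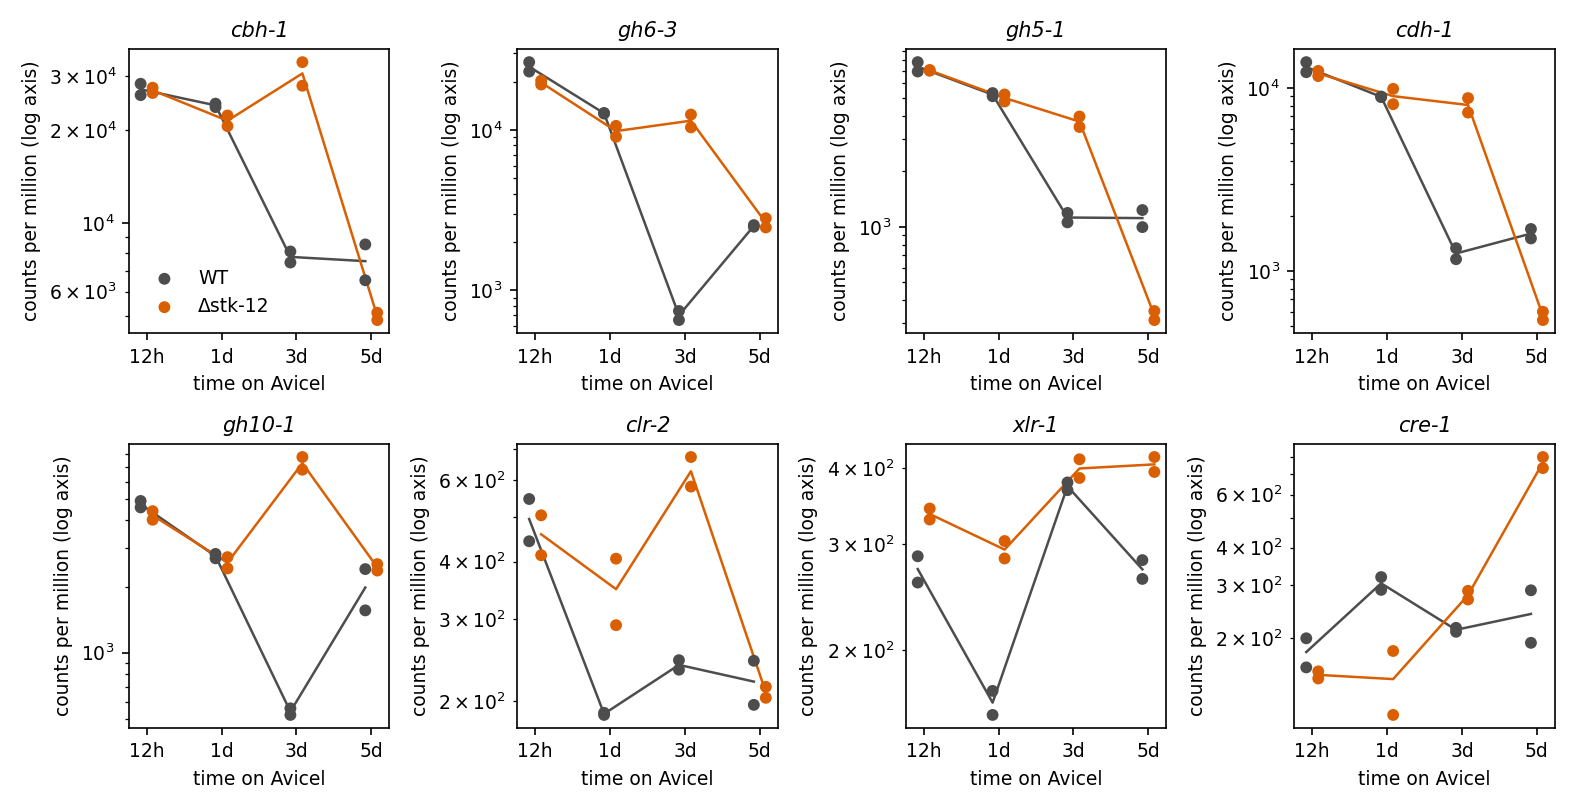
Levels of 5 enzyme genes (cbh-1, gh6-3, gh5-1, cdh-1 and gh10-1) and 3 regulators (clr-2, xlr-1 and cre-1) in each library, in CPM on log axes. Lines join the means of 2 libraries.

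Genes of protein folding, secretion and synthesis were higher with the enzymes at 3d. All 7 ER folding genes rose (median 0.86), with the chaperone grp78 at 1.08 and calreticulin NCU09265 at 1.09. In the secretory pathway 32 of 38 genes rose and 1 fell (median 0.39), with the translocon subunit sec61-1 at 1.28. Of 77 ribosomal proteins 70 rose and 3 fell (71 and 3 over the list alone; median 0.57), with crp-56 at 0.80 and NCU04614 at -0.69. Of 56 respiratory genes 48 rose and 0 fell (49 and 0 over the list alone; median 0.45), with cox-6 at 0.87. Of 11 glycolysis genes 9 rose and 0 fell (median 0.75), with gpi-1 at 1.51 and the enolase emp-7 at 1.13. The camera adjusted p was 0.00849, 0.000226, 2.41e-07, 1.09e-05 and 0.00137 in that order, and 0.393, 0.3, 0.651, 0.506 and 0.502 with an estimated correlation. With library totals alone 4, 19, 65, 37 and 8 genes of these lists rose and 0, 3, 4, 0 and 0 fell. Of 30 proteasome genes 16 rose and 2 fell (camera adjusted p = 0.25) and of 86 peptidases 34 rose and 16 fell (camera adjusted p = 0.335), but with library totals alone these became 2 and 6, and 22 and 33. Ribosome biogenesis genes turned too, from 7 risen and 5 fallen (5 and 3 over the list alone) to 2 and 10. Of the peptidases, NCU05980 fell by 5.54 and NCU06720 rose by 2.80.

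Other lists at 3d did not pass as groups but held large single changes. Of 14 conidiation genes 10 fell and 3 rose (median -0.61; camera adjusted p = 0.0791): eas stood at 23.1 ± 3.17 against 828 ± 3.32 CPM (-5.16) and con-10 fell by 2.49, while ccg-9 rose by 0.90. Cell wall genes fell in 15 of 30 cases and rose in 3 (camera adjusted p = 0.204), with gel-4 at -2.03, gh16-7 at -1.38 and the chitinase gh18-9 at 1.87, and histone and replication genes fell in 20 of 34 cases and rose in 4 (camera adjusted p = 0.172). Of 6 starch and sucrose enzymes 3 rose, with NCU08746 at 3.73 (camera adjusted p = 0.14), and with library totals alone 1 rose and 1 fell. Of 7 genes of gluconeogenesis and C2 metabolism 5 rose and 1 fell, with acu-3, isocitrate lyase, at 0.97 (camera adjusted p = 0.179), and of 14 heat shock genes 9 rose (9, with 1 fallen, over the list alone; 5, with 3 fallen, with library totals alone; camera adjusted p = 0.21). The largest rises were the copper transporter gene tcu-1 (8046 ± 739 against 28.5 ± 1.89 CPM; 8.14 ± 0.244), its neighbour NCU00829, a ferric reductase gene (8148 ± 484 against 53.7 ± 2.01 CPM; 7.24 ± 0.223), mfa-1 (8.33), the phospholipase gene NCU06650 (245 ± 22.6 against 1.00 ± 0.0955 CPM; 7.91) and NCU01212, which had 0 reads in WT and was at least 690-fold higher (91.2 ± 13.5 CPM). Neighbouring genes can share reads where the counting was not specific to the strand. The largest falls were the mating type genes, ccg-4 and NCU09968 (at least 1052-fold).

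At 3d, 5342 genes differed, 2645 higher and 2697 lower (593 and 886 at least 2-fold). With library totals alone the split was 1648 and 4249.

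At 5d the enzymes had turned. The cellulases took 1.23 ± 0.0408% of counts in the mutant and 2.05 ± 0.251% in WT, and 7 of 9 fell and 0 rose (median -1.04). cbh-1 stood at 4989 ± 192 against 7533 ± 1417 CPM (-0.59 ± 0.111, edgeR adjusted p = 0.000236), gh5-1 at 331 ± 26.5 against 1116 ± 167 CPM (-1.75 ± 0.108) and the endoglucanase gh45-1 lower still (-2.50 ± 0.123), whereas gh6-3 did not pass (0.07, adjusted p = 0.604). Of 15 oxidative genes 14 fell (median -0.75), with cdh-1 at -1.49, gh61-5 at -1.22 and gh61-11 at -2.18. The camera adjusted p was 9.18e-05 for cellulases and 0.000614 for oxidative genes, and 0.524 and 0.506 with an estimated correlation. Of 24 hemicellulases 15 fell and 4 rose (median -0.62; camera adjusted p = 0.0635, and 0.0471 with library totals alone), with gh11-1 at -1.69, the feruloyl esterase fea-1 at -2.17 and NCU09416 at -2.15 against gh43-4 at 1.36 and NCU08785 at 1.80.

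cre-1 stood at 766 ± 45.8 against 241 ± 67.5 CPM at 5d (1.67 ± 0.185), xlr-1 rose by 0.58, and clr-1 (0.05) and clr-2 (-0.08) did not pass. Of 10 regulators 4 rose and 1, rca-1 (-2.37), fell (camera adjusted p = 0.547), col-26, an activator of starch-degrading enzymes, at 0.97 and vib-1 at 0.98 among the rises, and their median of 0.03 turned to -0.07 with library totals alone. Starch and sucrose enzymes rose in 5 of 6 cases and fell in 1 (median 1.40), with NCU08746 at 1.86 and the glucoamylase gla-1 at 1.42 (camera adjusted p = 0.0145; adjusted p = 0.248 with an estimated correlation). cfp, which had been lower in the mutant at 1d, stood at 2267 ± 270 against 125 ± 6.36 CPM (4.19 ± 0.177), and all 11 glycolysis genes rose (median 0.65), with gpd-1 at 1.84 (camera adjusted p = 1.91e-05; adjusted p = 0.359 with an estimated correlation). Genes of gluconeogenesis and C2 metabolism rose in 6 of 7 cases and fell in 1 (median 0.69), with acu-6 at 2.27 and acu-9 at 1.41 (camera adjusted p = 0.0117; adjusted p = 0.359 with an estimated correlation).

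Respiratory genes rose in 32 of 56 cases and fell in 4 (33 and 4 over the list alone, 18 and 5 with library totals alone; median 0.20; camera adjusted p = 0.0348; adjusted p = 0.735 with an estimated correlation, and 0.0512 with library totals alone). Ribosomal proteins rose in 35 of 77 cases and fell in 8 (34 and 8 over the list alone, 21 and 14 with library totals alone; camera adjusted p = 0.111). Histone and replication genes rose in 19 of 34 and fell in 3 (camera adjusted p = 0.0862), with histone H1 (hH1) at 0.88, and light response genes rose in 6 of 8 (camera adjusted p = 0.0525, and 0.0414 with library totals alone), with the photoreceptor wc-1 at 1.12. Of 14 conidiation genes 5 rose and 5 fell, with the conidiation regulator fl at 1.85, ccg-9 at 1.35, eas at -3.82 and con-13 at -2.58 (median 0.19, mean -0.33, camera downward at adjusted p = 0.964). Of 7 beta-glucosidases 3 rose and 3 fell (median 0.12, mean -0.33, camera downward at adjusted p = 0.547). Of 10 transporters 3 rose and 4 fell (camera adjusted p = 0.51), and of 6 pectin enzymes 2 rose and 4 fell (camera adjusted p = 0.904). ER folding genes split as 3 risen and 3 fallen, with eor-1 at 2.21, secretory pathway genes as 11 and 7 (median 0.05, mean -0.00, camera upward at adjusted p = 0.749), and ribosome biogenesis genes as 11 and 7, and each became mostly lower with library totals alone (1 and 3, 5 and 15, 6 and 9). Proteasome genes rose in 4 and fell in 12 of 30 cases (camera adjusted p = 0.385). Peptidases rose in 30 and fell in 25 of 86 (30 and 26 over the list alone; median and mean -0.01, camera upward and not past the test), which became 25 and 32 with library totals alone. Heat shock genes rose in 6 and fell in 1 of 14 (camera adjusted p = 0.376), with a median of 0.05 that turned to -0.05 with library totals alone, and cell wall genes rose in 8 and fell in 12 of 30 (10 and 12 over the list alone), with the exochitinase gene Nag-1 at -1.39. The largest rises beside mfa-1 were NCU00732, annotated as a trichothecene hydroxylase (395 ± 17.3 against 1.85 ± 0.851 CPM; 7.73), NCU16673 (6.65), NCU04276 (5.59) and NCU17250 (5.56), and NCU05707 fell by 8.20 (0.661 ± 0.00269 against 196 ± 48.7 CPM).

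At 5d, 5530 genes differed, 2751 higher and 2779 lower (462 and 981 at least 2-fold). With library totals alone the split was 2046 and 3315.

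**Figure D5:**
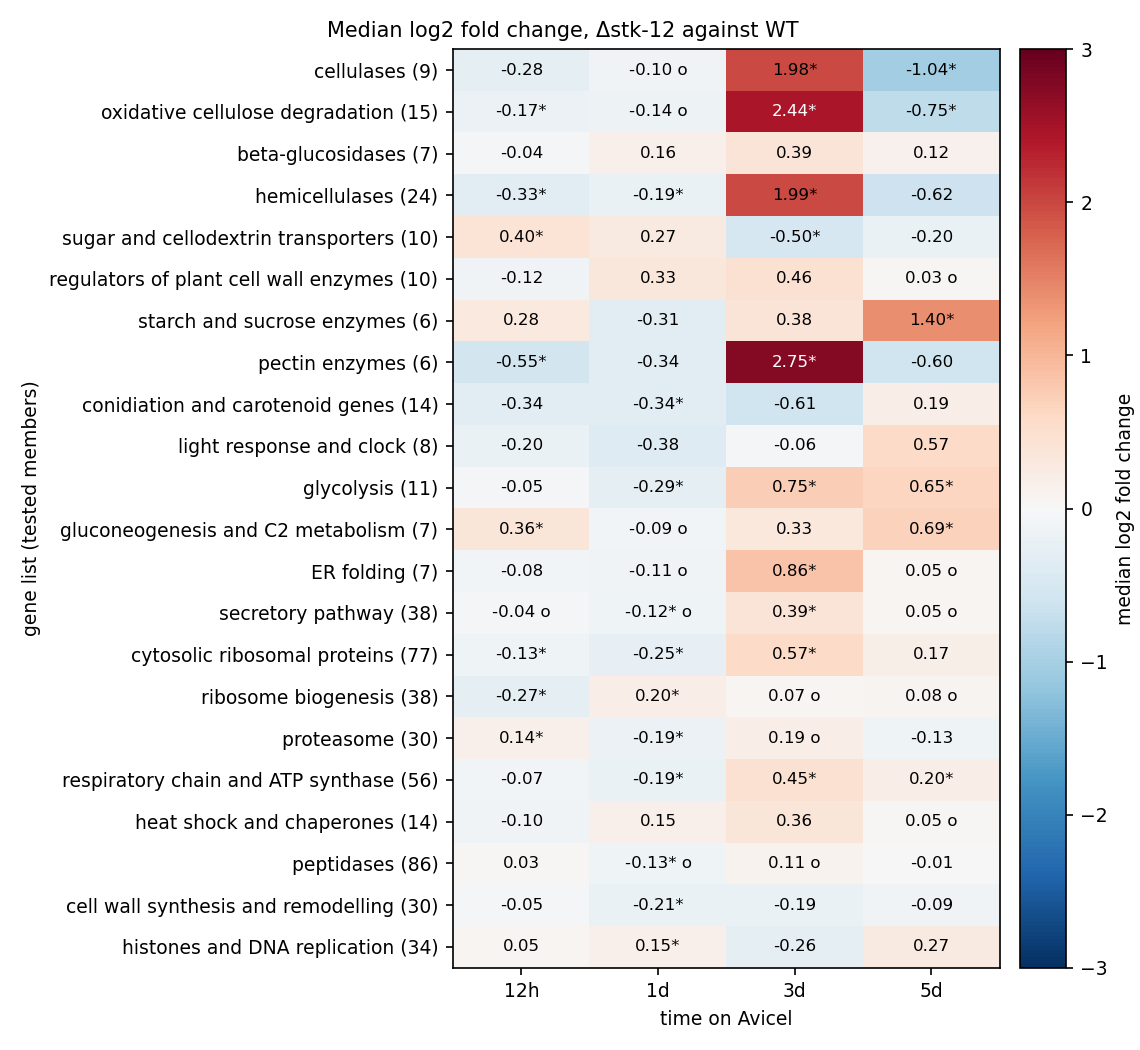
Median log2 fold change, mutant against WT, of 22 of the gene lists at each time, with an asterisk where camera with the preset correlation passed an adjusted p of 0.05. An o marks medians whose sign turned when libraries were scaled by totals alone; none of the calls shown held with an estimated correlation.

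Averaged over the 4 times, the differences at 3d and 5d partly cancelled. cbh-1 was 0.30 ± 0.0554 higher (log2, adjusted p = 0.000236), gh6-3 0.85 ± 0.0536 and gh10-1 0.95 ± 0.0704 higher, while gh5-1 (-0.04, adjusted p = 0.576) and gh1-1 (-0.09, adjusted p = 0.195) did not pass. Of 9 cellulases 6 rose and 2 fell (camera adjusted p = 0.175). Of 24 hemicellulases 13 rose and 5 fell (14 and 5 over the list alone), with NCU08785 at 1.44 and gh54-1 at -0.84, and the camera adjusted p was 0.0478 (0.786 with an estimated correlation). Starch and sucrose enzymes (4 of 6 rose, 1 fell; camera adjusted p = 0.0348), glycolysis (9 of 11 rose; 0.0051), gluconeogenesis and C2 metabolism (5 of 7 rose; 0.0304) and respiratory genes (32 of 56 rose, 1 fell; 0.0304) lay higher, and conidiation genes (2 of 14 rose, 8 fell; 3 and 8 over the list alone; 0.033) and cell wall genes (4 of 30 rose, 17 fell; 4 and 19 over the list alone; 0.0472) lower. Their adjusted p was 0.3, 0.598, 0.408, 0.735, 0.693 and 0.693 with an estimated correlation. Genes with the same sign at every time included NCU06650 (3.65), tcu-1 (2.59) and NCU01298 (2.37) among the rises, while eas (-2.87), NCU05980 (-4.03), rca-1 (-1.42), NCU00821 (-1.20) and gel-4 (-1.16) were lower on average. In all, 4807 genes differed on average, 2592 higher and 2215 lower (95 and 280 at least 2-fold), and with library totals alone the majority turned, to 2143 higher and 2554 lower.

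The genotype difference was tested for equality over the 4 times and was unequal for 6962 of 8983 genes. Genes that differed in the same direction at 3d and 5d numbered 2639, against 1644 for independent calls, and 927 differed in opposite directions, 7 of the 9 cellulases among them. Between 12h and 1d, 494 shared a direction (218 for independent calls), and between 1d and 3d 979 did (992) and 1116 were opposite (992). The log2 fold changes of 3d and 5d correlated with r = 0.593 over genes, and those of 12h and 1d with r = 0.332. Both r include the mating type genes, such as ccg-4 (-15.5 at 12h and -13.1 at 1d) and mfa-1 (12.1 and 9.87). Changes of that size weigh heavily in r, and no r without them was computed.

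Within WT, cellulose-degrading enzymes were high early and fell between 1d and 3d. From 12h to 1d gh6-3 (-0.96), gh11-1 (-1.45) and clr-2 (-1.40) fell, while cre-1 rose by 0.76 and cbh-1 did not pass (-0.17, adjusted p = 0.197). Of 24 hemicellulases 16 fell and 3 rose, of 38 ribosome biogenesis genes 25 fell and of 77 ribosomal proteins 49 fell and 1 rose, whereas 21 of 30 cell wall genes and 17 of 30 proteasome genes rose. The uncharacterised genes NCU16673 (8.29), NCU06940 (7.55) and NCU09604 (7.12) rose most, and NCU08533 (-6.98), NCU05629 (-4.91) and NCU06140 (-4.64) fell most. In this step 5103 genes differed, 2349 higher and 2754 lower.

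From 1d to 3d cbh-1 fell from 24100 ± 438 to 7776 ± 453 CPM (-1.63 ± 0.114, edgeR adjusted p = 9.38e-10), gh6-3 (-4.18), cdh-1 (-2.84), gh1-1 (-2.70) and gh10-1 (-2.35) fell as well, and xlr-1 rose by 1.19. Of 9 cellulases 7 fell and 1 rose, of 24 hemicellulases 22 fell and 1 rose, and all 11 glycolysis genes and all 7 ER folding genes fell. Ribosomal proteins fell in 74 of 77 cases, secretory pathway genes in 35 of 38, respiratory genes in 53 of 56 and proteasome genes in 27 of 30, while 8 of 14 conidiation genes rose and 3 fell. Peptidases (30 risen, 44 fallen), cell wall genes (7 and 11), histone and replication genes (6 and 20) and transporters (4 and 5) turned with library totals alone, to 45 and 26, 20 and 8, 14 and 8, and 5 and 2. gh7-1 (-0.43), gh3-4 (-0.49) and cre-1 (-0.51) also fell, but these calls ended with library totals alone (0.06, -0.00 and -0.02). The genes NCU08812, NCU08813 and NCU16924 had 0 reads at 1d and were at least 355, 173 and 128-fold higher at 3d, and NCU06912 (-7.65), NCU09798 (-6.23) and the invertase gene inv (-6.03) fell most. In this step 7099 genes differed, 3765 higher and 3334 lower, a split of 5467 and 2010 with library totals alone.

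From 3d to 5d the WT levels of cbh-1 (-0.05, adjusted p = 0.746) and gh5-1 (-0.01, adjusted p = 0.939) did not pass, while gh6-3 rose by 1.85, gh10-1 by 1.87 and gh11-1 by 2.26. Of 9 cellulases 6 rose and 0 fell, and of 24 hemicellulases 12 rose and 8 fell. cdt-2 (-1.41), cdt-1 (-1.12) and gh1-1 (-1.69) fell. So did 7 of 10 regulators, 29 of 34 histone and replication genes and 45 of 77 ribosomal proteins. The polyketide synthase gene pks-3 (-5.36), NCU05699 (-5.02) and NCU05631 (-4.74) fell most, and NCU05788 rose by 5.69, NCU09184 by 5.43 and the glucanase gene gh64-2 by 5.18. In this step 4905 genes differed, 2436 higher and 2469 lower, which became 2762 and 2105 with library totals alone.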

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

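The tests of the cellulase time course below were chosen only after the result was seen; the test of the genotype difference over the 4 times and the chance splits were fixed before.

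Each result here was set apart because the genotype difference itself differed between times, in the F test over the 4 times or in a camera test between consecutive times. No library was tested for lying far from its group, since 2 libraries that differ do not show which is out of place; the widest pairs were WT 5d and mutant 1d (chi-square per degree of freedom 22.6 and 18.0, against at most 10.8 in the others). Of the genes, 6962 of 8983 passed the F test in edgeR, among them all but 14 of the 205 named genes outside stk-12 and the panel (191). The adjusted p was 6.31e-05 for stk-12, whose difference was largest at 1d (-2.03) and smallest at 5d (-1.21). For enzymes it was 3.54e-09 (cbh-1), 1.74e-09 (gh6-2), 1.46e-10 (gh5-1), 3.01e-12 (gh6-3), 3.24e-10 (gh7-1), 4.81e-08 (gh3-4), 5.18e-07 (gh1-1), 1e-10 (gh61-5), 5.5e-09 (gh61-1), 3.25e-11 (cdh-1), 2.13e-10 (gh10-1) and 1.07e-10 (gh11-1). For transporters it was 0.00252 (cdt-1) and 6.78e-05 (cdt-2), and for regulators 8.13e-05 (clr-1), 1.05e-05 (clr-2), 6.92e-05 (xlr-1) and 1.21e-06 (cre-1).

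Between 1d and 3d the mutant's difference from WT moved upward for cellulases (camera adjusted p = 1.34e-11), oxidative genes (4.78e-17), hemicellulases (1.07e-24), pectin enzymes (1.04e-10), glycolysis (1.17e-07), gluconeogenesis and C2 metabolism (0.0464), ER folding (0.00026), the secretory pathway (3.73e-06), ribosomal proteins (1.17e-13), the proteasome (0.0253), respiratory genes (3.25e-09) and peptidases (0.0221), and downward for transporters (0.00174) and histone and replication genes (0.00938). Between 3d and 5d it moved downward for cellulases (5.64e-31), oxidative genes (3.31e-31), beta-glucosidases (0.0263), hemicellulases (1.8e-29), pectin enzymes (1.24e-08), ER folding (0.0331), the secretory pathway (0.000432), ribosomal proteins (0.000227), the proteasome (0.0334) and respiratory genes (0.018), and upward for conidiation (0.0487), light response (0.0461) and histone and replication genes (0.00147). Between 12h and 1d it moved upward for ribosome biogenesis (4.34e-08), and downward for conidiation (0.0487), glycolysis (4.97e-05), gluconeogenesis and C2 metabolism (0.000227), ribosomal proteins (0.00975), the proteasome (1.91e-07), respiratory genes (0.0213), peptidases (2.42e-05) and cell wall genes (0.00289). With an estimated correlation, 3 of these 36 differences passed: pectin enzymes between 1d and 3d, and cellulases and oxidative genes between 3d and 5d, each at an adjusted p of 0.0372.

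The pattern that most invites a closer look is that of the cellulases, higher in the mutant at 3d and lower at 5d. Whether the mutant 3d libraries belonged to another time of the mutant was tested by their nearness to WT libraries. Of 6 libraries of mutant 1d, 3d and 5d, 0 lay nearer to WT of the time exchanged than to their own. Over all genes, mutant 1d correlated with WT 1d at r of at least 0.978 and with WT 3d at 0.870 at most. This argued against an exchange of mutant 1d and 3d. Mutant 3d correlated with WT 3d at r of at least 0.920 and with WT 5d at 0.916 at most. Mutant 5d correlated with WT 5d at 0.930 or more and with WT 3d at 0.908 at most. The margin for mutant 3d was narrow, and the test assumes that the mutant follows the WT course. It therefore cannot decide on an exchange of mutant 3d and 5d, and 12h was not tried. That WT held more conidia at 3d cannot be told apart, because the conidiation list had a median of -0.61 with members both ways (SD 1.70; 10 lower, eas among them, and 3 higher). That the mutant passes through the WT course later may account for part of it: over all genes, the 3d difference correlated with the WT change from 1d to 5d at r = -0.365 (-0.334 and -0.386 with replicates of each number alone, r squared 13.3%), against -0.0324 for the WT change from 12h to 1d, and the 5d difference correlated with the WT change from 1d to 3d at r = -0.369, and the mutant change from 3d to 5d with it at r = 0.347. The cellulase share of counts in the mutant at 3d (6.36 ± 0.518%) lay within the WT range (up to 6.45 ± 0.336%, at 12h). At 5d the mutant share (1.23 ± 0.0408%) lay below WT at every time sampled (lowest 1.71 ± 0.0590%, at 3d). WT may have gone lower between the times sampled, so the 5d level cannot decide on a delay alone. Mating type or strain background in place of the loss of stk-12 cannot be told apart, because 0 of 16 libraries had genotype and mating type transcripts uncoupled.

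For the calls averaged over the 4 times, 100 splits of the libraries within the times were drawn from 648 possible. Only the real one (1 split) called as many genes, 4807. The highest other split called 4420 and kept the genotype grouping at 3d and 5d, and the median of the others was 2. A chance assignment of these libraries to the genotypes was thus argued against. The labels do not say that replicates were separate cultures, so the splits cannot exclude chance differences between cultures.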

How the results depend on the processing

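The results without the mating type genes and over 3 of the 4 times were chosen only after the result was seen; the other alternatives were planned. No list test that passed reversed in direction, but camera compares a list with other genes, so a shift of all genes by the scaling largely cancels. The members of the secretory pathway, proteasome and peptidase lists at 1d, which passed, did turn on balance with library totals alone. Of the named genes past the test, gh7-1 in the WT step from 1d to 3d turned with totals (-0.43 to 0.06) and no longer passed. The near-even split of calls into higher and lower turned in places, among them the mean, from 2592 and 2215 to 2143 and 2554 with totals, and, in DESeq2, 12h from 587 and 585 to 531 and 653, 1d from 1718 and 1619 to 1430 and 1764, and 3d from 2645 and 2697 to 2693 and 2376. The 9 counts of genes stayed within 1.5 times under DESeq2 size factors, totals alone, no filter, DESeq2, limma voom, and the replicate block. So did 7 of them in a fit to only the groups compared. The 5 genotype counts without the mating type loci did too. Leaving out 101 of 8983 genes could hardly move them that far, so that setting says little on the strain difference. Leaving out single libraries moved 12h (463 to 1015) and 1d (2100 to 3073) further; there the lone sample was assumed to vary like the other groups, and fewer libraries alone lower such counts. Means over 3 times called 5267, 5289, 4090 and 3879 genes without 12h, 1d, 3d and 5d. With the replicate block, the genotype calls were 1164, 3327, 5319, 5495 and 4805 in order of time and for the mean; the deviations of replicate 1 correlated between 28 pairs of groups with a median r of -0.00645 (-0.145 to 0.0891).

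For the cellulase list, the call at 3d ended with an estimated correlation (adjusted p = 0.248), as did that at 5d (0.524), because the estimate allows for members that move together, and fry alone called the mean of the 4 times (0.0128). Leaving out single libraries kept both calls (1.34e-15 to 1.04e-10 at 3d, 1.65e-06 to 0.000321 at 5d). Over all 115 list tests, the estimated correlation ended 45 calls; fry added 38 and ended 1, totals alone added 6 and ended 3, and the block ended 3. The causes of the last 3 were not tested. Counting each named gene at each genotype contrast it was named for, DESeq2 kept 445 on their side of the threshold, added 4 and ended 5, and the block kept 449 and ended 5. In simulated data 24 to 32% of the smallest changes were recovered. Depth and group size were not varied there, and far fewer genes were called than in the real data.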

Other observations

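The tests of the mating type difference were chosen only after the result was seen, and those of copper and iron were written down before their genes were looked up. The copper and siderophore genes were chosen after tcu-1 and NCU00829 had been seen, and sod-2, NCU09969, NCU16528 and the genes near the mating type locus after their own values were seen.

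Genes of iron uptake and the superoxide dismutase gene sod-2 stood apart in the mutant at 3d. The siderophore transporter NCU06132 stood at 245 ± 31.0 against 35.4 ± 2.61 CPM (mean ± SD, n = 2; log2 fold change 2.79), the siderophore synthesis gene NCU06062 at 183 ± 2.76 against 15.2 ± 1.80 CPM (3.59), the ornithine oxygenase NCU07117 at 51.8 ± 4.16 against 12.9 ± 0.940 CPM (2.00), and the iron permease trm-51 at 58.3 ± 1.15 against 16.4 ± 0.834 CPM (1.83). The siderophore transporter NCU07564 rose by 1.84, and NCU08167 did not pass at 3d (0.19, edgeR adjusted p = 0.089) but rose by 1.14 at 5d, when NCU06132 (2.13) and trm-51 (2.31) were also higher. Earlier calls went both ways. At 12h NCU06062 (-0.47) was lower and trm-51 (0.69) higher. At 1d NCU08167 (-0.80) and trm-51 (-0.64) were lower, and NCU06132 (0.38), NCU07117 (0.31) and NCU07564 (0.21) higher. sod-2 rose by 4.75 (2394 ± 145 against 88.8 ± 4.95 CPM) beside its neighbour NCU01212, and the copper metallothionein gene cmt rose by 0.32 at 3d and by 1.85 at 5d (561 ± 7.99 against 155 ± 14.8 CPM). The strand of counting was not given, so the values of neighbouring genes are uncertain.

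Genes that differed at least 2-fold in 1 direction at all 4 times numbered 20, of which 14 lay on chromosome I. The window of 101 genes that held most of them there was picked by its count. It held 11, the mating type A genes among them, with matA-1 at its end. On chromosome I were the DNA lyase NCU01961 next to the mating type locus (-1.55, -1.53, -1.84 and -1.92 at 12h, 1d, 3d and 5d), NCU01946 (-5.52, -3.03, -5.70 and -5.96), NCU02058 (-2.76, -2.73, -3.37 and -3.17) and mus-42, a DNA polymerase of lesion bypass (-1.97, -1.24, -2.46 and -1.55). On other chromosomes were NCU05980, mfa-1, pre-2, and NCU09968, NCU09969 and NCU16528, which had 0 reads in the mutant, NCU09969 at least 24.8 to 75.8-fold and NCU16528 at least 22.8 to 56.1-fold lower.

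The absence of mating type A transcripts in the mutant may mean that the mutant strain carries mating type a. The smallest log2 fold change of the mating type a pheromone gene mfa-1 over the 4 times was 7.34, which that explanation needs. Exchange of libraries between the genotypes was argued against, since 0 of 16 libraries were out of place for mating type A reads or stk-12. A chromosome segment around the locus that differs between the strains stays open as well: with the mating type A genes left out, 3 of 95 genes within 50 loci of matA-1 were changed at all times, against 14 of 8885 elsewhere (odds ratio 20.7, Fisher p = 0.0007), while around stk-12, itself left out, it was 0 of 90. That test was chosen after these genes were seen, so its p is no independent evidence for a segment. The 14 genes elsewhere included stk-12, mfa-1 and pre-2. They also held most of the other genes in the window of 101 that ended at matA-1, so they were no plain background.

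The rise of tcu-1 and NCU00829 at 3d could reflect a shortage of metal in the mutant culture. For iron, the 6 siderophore and uptake genes had a median log2 fold change of 1.92 at 3d (SD 1.14, range 0.19 to 3.59). Of these, 5 were higher past the test, as that explanation needs. For copper, the 5 genes of copper-carrying proteins had a median of 0.0025 with 2 higher and 2 lower (SD 0.890), and members that go both ways leave it undecided: sod-1 (-0.51) and NCU05512 (-1.62) fell, and NCU07851 (0.66) and cmt rose. A median of 0 or above had been set beforehand as speaking against copper shortage, and the median met that bound. It lay above 0 by far less than the spread of the 5 genes, so it was not taken to decide. The iron genes spread as widely, but their lowest value was 0.19. No metal was measured, and tcu-1 at 12h (0.21, adjusted p = 0.533) and 1d (0.28, adjusted p = 0.394) did not pass. At 5d tcu-1 was higher in the mutant by 1.73 (1325 ± 11.3 against 398 ± 171 CPM; edgeR adjusted p = 5.68e-07). WT had held 28.5 ± 1.89 CPM at 3d, so a rise of tcu-1 was not confined to the mutant.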
